A study of Mus musculus with 13 samples.

How the data were processed

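The series holds 13 samples, of which 9 are RNA-seq libraries and 4 are ATAC-seq libraries of sorted fractions, and each group is 1 library. Only the RNA-seq table was used, and the ATAC-seq samples were not analysed here. Samples were placed in groups from their titles alone. The labels do not tie the RNA-seq libraries to a particular medium or oxygen level beyond the treatments named, and no comparison uses such a difference.

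The deposited RNA-seq table gives estimated counts per gene symbol for 30332 genes, with 1 column per library. Its values sum to between 20104940 and 36751356 per library and include fractional numbers, so they were read as estimated counts and not as TPM, the unit the analysis plan had assumed. Per the submitters' processing notes, the series was processed with kallisto 0.43.1, Bowtie2 2.2.9, SAMtools 1.3.1, deepTools 2.4.2, MACS2 2.1.1.20160309 and bedtools 2.25.0 on the builds GRCm38 and mm10. The annotation used for quantification, and how transcripts were summed to genes, are not given in the sources used here. Of the symbols, 29890 matched a reference gene table of assembly GRCm38.p6, from which gene positions were taken. That table was the source of positions only, and each position is the span of the whole gene.

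CPM, the usual count scaled to library size, were computed from a gene's estimated count and the total of its column, and every threshold planned for TPM was applied to CPM unchanged. CPM does not correct for transcript length, so levels of different genes within a library are not compared. Differences are of log2(CPM + 1), a scale that understates changes of low genes. A gene was called higher or lower at a difference of 1 or more (2-fold) among genes with 5 CPM or more in at least 1 of the 2 libraries. Ratios printed as folds are ratios of CPM without a pseudocount, with exact conditional binomial 95% intervals on counts rounded to whole numbers, and intervals of single CPM values are exact Poisson intervals. A library's floor was 3 counts. With 1 library per group no p-values or standard deviations are given. A model with fraction and day as terms over the 4 sorted D4 and D8 libraries, which would take the days as replicates, was not run.

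A set of 41 gene lists was fixed, with the pluripotency, germline and housekeeping lists as ones with no stated tie to the treatment. For each list the median difference over members with 1 CPM or more in any library was set as a percentile among 10000 random lists of the same size, matched on mean expression in 20 bins, and the list was called shifted at a percentile in the outer 2.5% on either side. Members counted as higher or lower in a list were 2-fold apart on the log2 scale among those members, without the 5 CPM floor of single genes. The percentile describes these libraries and is not a p-value. Of all list members, 1 was not in the table. Named genes followed a rule with 3 parts: 8 study factors throughout, up to 4 members of each shifted list with the largest difference in its direction, and up to 6 highest and 6 lowest genes per comparison with 20 CPM or more in either library, leaving out predicted genes and pseudogenes by their symbols. For the fractions at both days the last part ranked genes by the smaller of their D4 and D8 differences. A gene named for one comparison may also be given in another. A few genes that the rule would name are not reported here. The lists, the rule, the 15 comparisons and most other settings were chosen before the data were examined.

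Similarity of libraries was taken as Pearson and Spearman correlation of log2(CPM + 1) over 17041 genes with 1 CPM or more in any library. The approach of each library to NSC was measured on genes at least 4-fold apart between NSC and D0, as the share moved 2-fold in the direction of NSC, beside genes outside both sets matched on their D0 level. The other settings were pseudocounts of 0.1 and 5, no filter or a floor of 1 CPM, median ratio scaling over 8290 genes with 5 CPM or more in every library, rescaling without mitochondrial, ribosomal protein and the 20 most abundant genes, quantile normalization, other member filters, the mean over members, and an 8-fold axis. TMM scaling, and quantile normalization of the list medians, were added after seeing the data.

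The calls were tested on simulated data for the comparison of the D4 fractions, over 10509 genes. Of 50 genes each, 50 changed 3-fold upward, 50 changed 4-fold upward, 49 changed 3-fold downward and 50 changed 4-fold downward were recovered, and 0 of 10310 unchanged genes were called. Unchanged genes of the simulated libraries differed by counting noise alone, which at the 5 CPM floor is too small for a 2-fold call. The 0 therefore gives no rate of false calls between separate libraries. Of 20 lists with raised members 20 were called, of 500 unchanged lists 22 (4.40%) were called, and 953 of 1000 ratio intervals (95.3%) held 1. Members of the unchanged lists also differed by counting noise alone, and the percentile cut largely sets the share of such lists called. The 4.40% therefore gives no rate of false calls for the fixed gene lists between separate libraries. Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9 and R 4.3.3 with edgeR 4.0.16, for TMM scaling alone, were used.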

Results

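RNA was sequenced from 9 cell populations that carry a Nestin-GFP transgene, in which green fluorescent protein reports the Nestin gene of neural stem and progenitor cells. Mouse embryonic fibroblasts grown to passage 3 were profiled before treatment (D0) and after 1 and 2 days (D1 and D2) with VCR. VCR combines valproic acid, an inhibitor of histone deacetylases, CHIR99021, an inhibitor of the kinase GSK3, and RepSox, an inhibitor of the type I TGF-beta receptor. After 4 and 8 days of VCR the cells were sorted into GFP-positive and GFP-negative fractions. The remaining libraries were sorted GFP-positive primary neural stem cells (NSC) and sorted GFP-positive cells from fibroblasts that received growth factors in place of the chemicals (GF). The GF protocol gave IL6 at 50 ng/ml for 2 days, FGF5 at 50 ng/ml with LIF at 100 ng/ml for the next 4 days, and then EGF and bFGF at 20 ng/ml each.

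Each of the 9 groups had 1 library, so there were no replicates and every difference compares libraries rather than conditions. The libraries held between 20104940 (NSC) and 36751356 (D0) estimated counts. The floor of 3 counts corresponded to between 0.0816 CPM in D0 and 0.149 CPM in NSC. All intervals are 95% intervals, and those of levels and ratios cover counting error only. Intervals of shares of genes are exact binomial intervals that take genes as independent, which they are not. None of the intervals covers the spread between separate libraries. Genes were called higher or lower at a 2-fold difference of log2(CPM + 1), and counting noise alone gave 0 calls in each of the 15 comparisons. Counting noise at the 5 CPM floor is too small for such a call, so the 0 does not measure the spread between separate libraries. D0 is shared by 8 of the comparisons, so anything peculiar to that library enters all of them. A further 4 ATAC-seq samples of the sorted fractions were not analysed here.

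The title of the series names growth factors and Nup210, which encodes a nucleoporin of the nuclear pore membrane. Il6, Fgf5, Lif, Nes and the SoxB1 transcription factor genes were followed with it in every library. Fgf5 was at 2.78 CPM at D0 and at 454 and 391 CPM in the GFP-positive libraries of D4 and D8, against 8.61 and 10.6 CPM in the GFP-negative ones. Its ratio between the D4 fractions was 52.8-fold (95% interval 46.3 to 60.1). Lif was at 38.6 and 48.3 CPM in the GFP-positive and 3.44 and 3.40 CPM in the GFP-negative libraries, and highest in GF at 257 CPM. Il6, which encodes an inflammatory cytokine, went from 6.01 CPM at D0 to 78.1 at D1 and 22.8 at D2. At D4 it stood at 21.5 CPM in the GFP-negative against 1.55 CPM in the GFP-positive library, and in GF at 82.2 CPM. Nes, the gene of the sorting reporter, reached 784 and 721 CPM in the GFP-positive libraries, above the 344 CPM of NSC. Sox2, a transcription factor gene of neural stem cells, reached 84.0 and 130.3 CPM there, against 267 CPM in NSC and 1.33 CPM at D0.

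Nup210 had 49 counts (1.41 CPM, interval 1.04 to 1.86) in the GFP-positive D4 library and 24 counts (0.831 CPM, interval 0.533 to 1.24) in that of D8. GF held 15 counts of it (0.677 CPM, interval 0.379 to 1.12). The D0, D1, D2 and GFP-negative libraries held between 0.122 and 0.149 CPM of Nup210, and NSC held 47.3 CPM (interval 44.3 to 50.4). The ratio of its CPM between the D4 fractions was 9.62-fold (95% interval 3.53 to 36.7). On the log2(CPM + 1) scale, which compresses such low levels, the difference was 1.07, and 0.90 with median ratio and 0.93 with TMM scaling, under the 2-fold mark. Its level lay under the 5 CPM that a call needed. Sox1 was at 52.6 CPM in NSC and at 1.17 CPM or less in every other library. Sox3 was at 5.77 CPM in NSC, 2.57 CPM in GF and 0.948 and 0.173 CPM in the GFP-positive libraries of D4 and D8. It had 0 counts at D0, at D2 and in both GFP-negative libraries. In GRCm38.p6, Nup210 spans chromosome 6 from 91013067 to 91118322, Fgf5 chromosome 5 from 98254184 to 98277033, and Lif chromosome 11 from 4257568 to 4272514. Il6 spans chromosome 5 from 30013114 to 30019975, Nes chromosome 3 from 87971093 to 87980451 and Sox2 chromosome 3 from 34649995 to 34652461. The annotation lists all of them as protein-coding. Taken as a list, the 8 genes had medians of 2.11 and 2.09 between the fractions at D4 and D8, 2.16 and 2.12 in the GFP-positive libraries against D0, 0.58 at D1, 4.04 in NSC and 2.22 in GF. The list holds Nes, whose reporter defined the fractions, so its shift between them was partly fixed by the sorting. At D4 its median lay between Nup210 (1.07) and Lif (3.16), while Il6 went the other way (-3.14). Nup210, Sox1 and Sox3 lay under 5 CPM in both fractions.

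**Figure D1:**
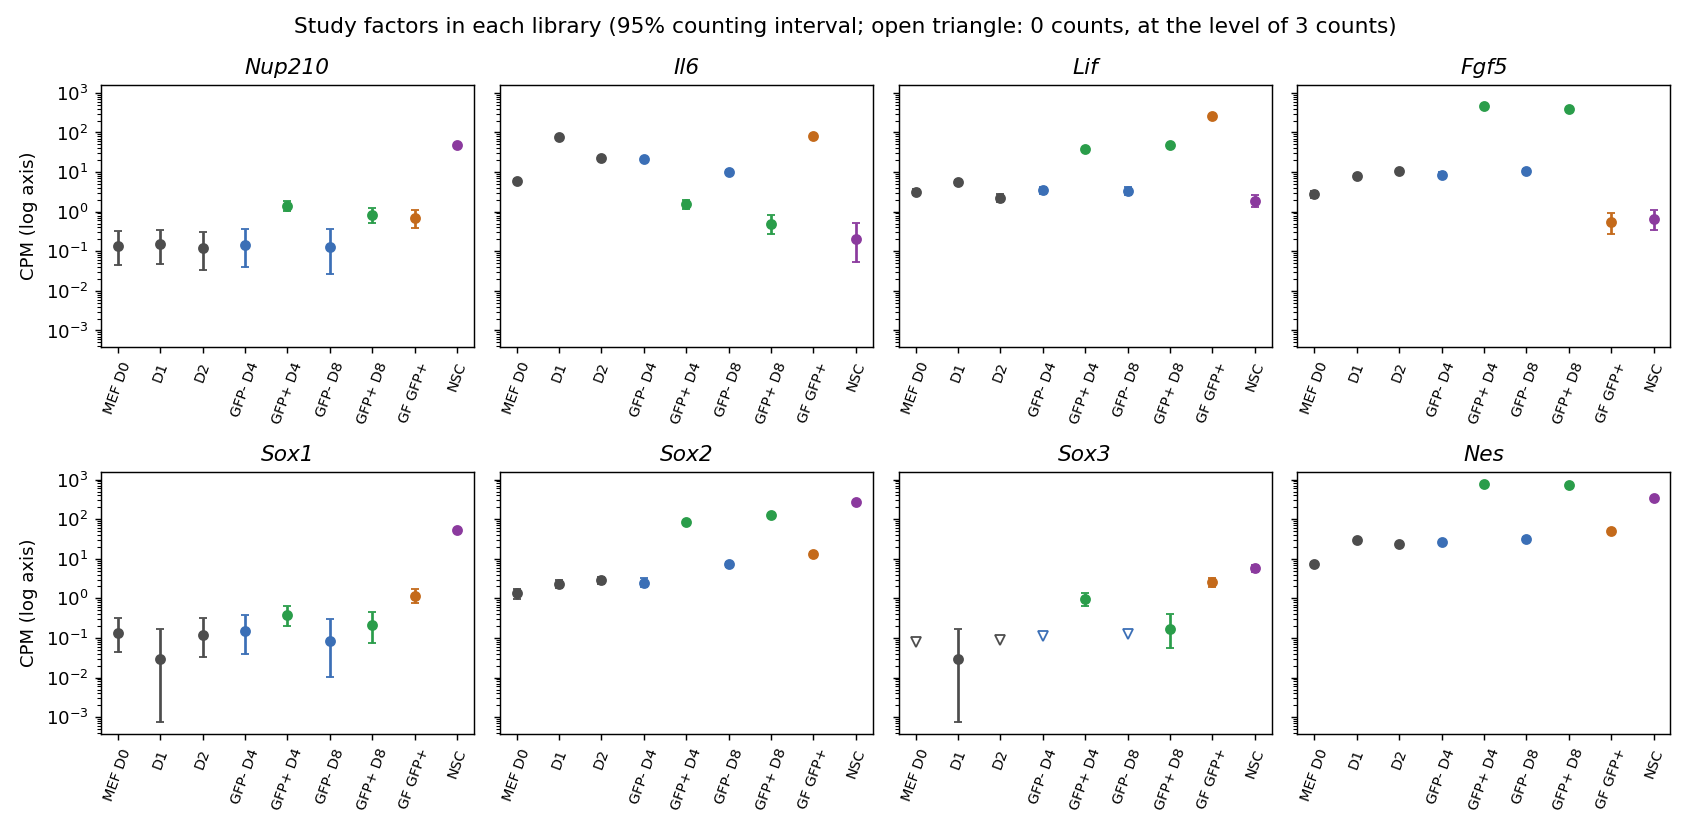
CPM on a log axis of 8 genes in each of the 9 libraries, with 95% counting intervals; an open triangle marks 0 counts, drawn at the level of 3 counts. Fgf5 stands at 454 and 391 CPM in the GFP-positive libraries of D4 and D8, and Nup210 at 47.3 CPM in NSC.

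The D1 and D2 libraries show how the culture differed from D0 before any sorting. The series holds no untreated library at D1, D2, D4 or D8. Effects of VCR therefore cannot be separated from those of time in culture and handling in any comparison with D0. At D1, genes of inflammatory cytokines and chemokines rose with Vip, Tslp and Stc1, genes of secreted signals, while genes of cholesterol synthesis fell. Cxcl1, a neutrophil chemokine, went from 30.6 to 455 CPM or 14.9-fold (95% interval 14.0 to 15.8), Vip, the vasoactive intestinal peptide, from 0.571 to 128 CPM, Tslp from 2.56 to 135 CPM and Stc1 from 3.86 to 153 CPM. Fdft1, the squalene synthase gene, fell from 259 to 38.0 CPM, and Insig1, a sterol-regulated brake on the pathway, from 69.5 to 4.99 CPM. Eln, which encodes elastin, fell from 87.9 to 4.01 CPM and on to 0.0913 CPM at D2. In all, 698 genes were higher and 623 lower at D1, and 711 higher and 637 lower at D2, of 10532 and 10547 compared.

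Of the cholesterol synthesis list, 16 of 19 measured members fell at D1 and 16 at D2, with medians of -1.86 and -2.01 on the log2 scale. The fibroblast list had 8 members lower and 2 higher at D1 (median -0.48) and 10 lower and 3 higher at D2 (median -0.68). Col1a1, the main collagen chain of connective tissue, stood at 5658, 1706 and 547 CPM on the successive days. The TGF-beta and contractile list changed the sign of its median between the days. The median was 0.37 at D1, where 2 members, Cnn1 (calponin, 4.21-fold) and Myl9 (2.62-fold), were higher and 3 lower, Pmepa1 falling from 339 to 76.2, Bhlhe40 from 112 to 18.3 and Skil from 34.1 to 10.0 CPM. At D2 the median was -1.09 and 10 of 18 members fell, among them Pmepa1 (8.02-fold lower) and Ctgf (7.56-fold lower). The cell cycle list turned as well, with 32 of 32 members above 0 and 3 past 2-fold at D1 (median 0.61; Tyms 2.56-fold higher). At D2 4 of its members were lower (median -0.68; Mki67 2.43-fold lower). Inflammatory genes had 7 of 16 members higher and 0 lower at D1 (median 0.54) and 5 higher and 1 lower at D2 (median 0.33), the D2 call being lost with a pseudocount of 5.

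Targets and receptors of IL6 and LIF signalling rose with 3 of 14 members at D1 (median 0.48) and 6 at D2 (median 0.84); Saa3, an acute-phase gene, went from 0.980 to 5.32 and 46.1 CPM. Targets of FGF and ERK signalling had 6 of 15 members higher at D1 (median 0.51), with Phlda1 5.46-fold higher. The neuronal list had a median of 0.33 at D1 with 6 of 17 members higher, among them Syn1, a synaptic vesicle gene (7.78-fold), and Gap43, a growth cone gene (4.45-fold). Nucleoporins had a median of 0.36 and 3 of 30 members higher at D1. Nuclear genes of oxidative phosphorylation lay above 0 in 19 of 19 members on both days (medians 0.37 and 0.69), while the mitochondrially encoded list fell with 5 and 4 of 13 members (medians -0.86 and -0.88). Interferon response genes fell with 4 of 15 members at D1 and 6 at D2 (medians -0.77 and -0.79). At D1 the hypoxia and glycolysis list fell (median -0.31, 4 of 18 members). At D2 the p53 list was higher (median 0.52; Mdm2 2.42-fold) and the unfolded protein list lower (median -0.43; Trib3 5.72-fold lower). Macrophage markers were lower on both days (medians -0.58 and -0.62; Lyz2 74.4, 39.5 and 46.5 CPM), and cartilage and bone genes at D2 (median -0.33).

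The sorted fractions were then set against D0, which asks how far each had left the starting state. D0 was not sorted, so sorting may enter every comparison of a sorted library with it. In the GFP-positive libraries, genes of the neural crest and of Schwann cells, the glia of peripheral nerves, were among the most raised. Sox10, a transcription factor gene of the neural crest, went from 2.94 CPM at D0 to 652 CPM at D4 and 748 CPM at D8. Erbb3, a neuregulin receptor gene of Schwann cells, went from 1.55 to 385 and 401 CPM. Dhh, a hedgehog ligand made by Schwann cells, went from 0.191 to 164 and 208 CPM. Matrix and contractile genes of the fibroblast fell: Aspn, a collagen-binding proteoglycan, from 643 to 0.201 and 0.208 CPM, S100a4 from 781 to 3.30 and 7.59 CPM, and Acta2, the smooth muscle actin, from 4957 to 93.3 and 40.6 CPM.

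Of 13 measured neural crest and Schwann genes, 10 rose at D4 (median 4.63, 4.20 with median ratio scaling) and 11 at D8 (median 5.43, 5.05), Cdh19 by 88.1-fold at D4. The neuronal list rose with 11 and 10 of 17 members (medians 1.80 and 1.56), led by Gap43 (42.9 CPM at D0, 1484 and 1779 CPM), Syp and Syn1. Neither the neural stem and progenitor list nor the cell cycle list was called shifted against D0 at D4 or D8. The oligodendrocyte list, which shares members with the neural crest list, Sox10 among them, had 6 of 13 members higher on both days (medians 0.92 and 1.00). Nucleoporins rose with 20 of 30 members at D4, Nup210 counted among them although under 5 CPM, and 16 at D8 (medians 1.33 and 1.12, 0.81 and 0.65 with median ratio scaling), with Nup205 at 13.52, 108 and 101 CPM. The fibroblast list fell with 19 of 25 members on both days (medians -1.83 and -2.09) and the TGF-beta and contractile list with 13 of 18 (medians -2.39 and -2.72). Cholesterol synthesis fell with 14 and 10 of 19 members (medians -1.72 and -1.28), ribosomal protein genes with 17 of 25 on both days (medians -1.15 and -1.13). Mitochondrially encoded genes fell with 13 and 12 of 13 (medians -1.81 and -1.45). Medians of Hox genes, which mark position along the body axis, were -0.41 and -0.39. Hoxc8 fell from 42.5 to 7.49 and 5.16 CPM. Among the growth factor genes, Igf2 fell from 1101 to 35.3 and 53.5 CPM. The list had 7 members higher and 10 lower at D4 (medians -0.34 and -0.47 at D4 and D8). Further lists below their random counterparts on both days were those of interferon response (medians -0.61 and -1.24), hypoxia and glycolysis (-0.59 and -0.85), oxidative phosphorylation (-1.12 and -1.22), keratinocyte (-1.19 and -1.40), adipocyte (-1.08 and -1.17) and cartilage and bone genes (-0.22 and -0.22), the last call being lost in 6 of 8 other settings on each day. Inflammatory, matrix protease and skeletal muscle genes were called lower at D4 (medians -0.43, -0.58 and -0.16), the last 2 calls being lost in 5 of 8 other settings each, and the unfolded protein list at D8 (median -1.23; Trib3 1.77 CPM against 128). Differences between the days in these lists were not tested.

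Prl2c2, Clca3a2 and Ccl6 also led the rise in the GFP-positive libraries (4473, 2007 and 291 CPM at D8). These genes belong to gene families, and their values are uncertain wherever reads were shared with near-identical copies. Sharing of reads was not tested. The median gene lay 0.66 above D0 at D4 and 0.57 at D8. In all, 4380 and 4038 genes were higher against 1289 and 1511 lower (77.3% and 72.8% of the changed genes higher). With median ratio scaling, which takes such a shift out, 2500 were higher and 2381 lower at D4 (51.2% higher) and 2579 and 2427 at D8 (51.5%). With TMM scaling 52.2% and 49.1% were higher. The list calls are made against random lists of the same libraries and are therefore relative to this shift, while the printed list medians include it.

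The GFP-negative libraries had fewer genes changed from D0 than the GFP-positive ones. Saa3 went to 83.9 and 72.4 CPM from 0.980, Aldh1a7, an aldehyde dehydrogenase gene, to 325 and 719.9 CPM from 5.71, and Socs3, a feedback inhibitor of STAT3 signalling, to 63.3 and 243 CPM from 16.5. In the GFP-positive libraries Socs3 was higher still, at 145 and 371 CPM, and Saa3 was at 34.1 and 6.62 CPM. Cell cycle genes fell with 19 and 20 of 32 members (medians -1.25 and -1.17), with Mki67, a gene of proliferating cells, 5.33-fold (95% interval 4.5 to 6.36) lower at D4. The p53 list rose with 6 and 4 of 16 members (medians 0.69 and 0.74), Mdm2, a p53 target that restrains it, by 4.58-fold and 2.67-fold. Receptors and targets of IL6 and LIF rose with 8 of 14 members on both days (medians 1.27 and 1.25) and immediate early genes with 7 of 12 (medians 1.23 and 1.41).

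At D8 the GFP-negative library also had 10 of 16 Wnt and beta-catenin targets higher (median 1.18), among them Axin2, the feedback gene of that pathway (0.327 to 8.59 CPM), and Nkd2 (29.1 to 324 CPM). Of 10 hedgehog genes 4 were higher (median 0.73; Gas1 133 to 1098 CPM). Cholesterol synthesis fell at D4 with 17 of 19 members (median -1.89), TGF-beta and contractile genes with 12 and 10 of 18 (medians -1.31 and -1.18). Fibroblast genes fell with 11 and 8 of 25 and rose with 5 and 7 (medians -0.64 and -0.36), Aspn standing at 2.60 and 2.08 CPM. The interferon list fell on both days (medians -0.61 and -1.02). Macrophage markers fell beside these groups (medians -0.94 and -0.59; Lyz2 14.5 and 7.19 CPM). At D4 nucleoporins were higher (median 0.61, 4 members past 2-fold) and mitochondrially encoded, cartilage and bone, and hypoxia and glycolysis genes lower (medians -0.37, -0.18 and -0.19), the last turning to 0.019 with quantile normalization and the cartilage and bone call being lost in 5 of 8 other settings. At D8 the unfolded protein, ribosomal protein, keratinocyte and skeletal muscle lists were lower (medians -0.80, -0.41, -0.70 and -0.23). The median gene lay 0.30 above D0 at D4 and 0.31 at D8, with 1184 and 1788 genes higher and 570 and 667 lower (67.5% and 72.8% higher). Median ratio scaling gave 637 higher and 877 lower at D4 (42.1% higher) and 1140 and 1077 at D8 (51.4%), and TMM scaling 45.6% and 44.8% higher.

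The direct comparison of the fractions at each day asks what set the GFP-positive cells apart from GFP-negative cells after the same days of treatment. Erbb3 was 118-fold (95% interval 96.1 to 147) higher at D4 and 90.6-fold (95% interval 74.7 to 111) higher at D8, and Sox10 71.6-fold (95% interval 63.2 to 81.5) and 52.2-fold (95% interval 46.9 to 58.3). L1cam, a neural adhesion gene, stood at 344 CPM against 5.58 at D4 and at 358 against 6.52 at D8. Adgrg1, an adhesion receptor gene, stood at 331 against 4.39 and at 348 against 5.45 CPM. Lower in the GFP-positive fraction were Mgp, an inhibitor of matrix calcification (17.1 against 673 CPM at D4), Igf2 (35.3 against 689.9 CPM), Cxcl1 (15.7 against 335 CPM) and Crabp1, a retinoic acid binding protein gene (88.4 against 1213 CPM). In GRCm38.p6, Sox10 spans chromosome 15 from 79154913 to 79164490, Erbb3 chromosome 10 from 128567523 to 128589635 and Cdh19 chromosome 1 from 110888002 to 110977601, all protein-coding.

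Of the neural crest and Schwann list 10 and 11 of 13 members were higher and 1 lower on each day (medians 3.94 and 4.27), with Cdh19, a cadherin gene of Schwann cell precursors, 51.3-fold and 60.1-fold higher. Cell cycle genes were higher with 27 and 26 of 32 members and none lower (medians 2.20 and 2.12), Mki67 at 65.7 against 5.63 CPM and Kif11, a mitotic motor gene, at 49.9 against 3.99 CPM at D4. Against D0 the cell cycle list was not called in the GFP-positive libraries (medians 0.98 and 0.90, percentiles 90.19 and 90.48). It was called lower in the GFP-negative ones (medians -1.25 and -1.17). Nucleoporins were higher with 15 and 11 of 30 members, Nup210 with its level under 5 CPM being 1 of those at D4 (medians 0.90 and 0.80). The neural stem and progenitor list was higher with 8 and 7 of 20 members and 3 lower on each day (medians 0.79 and 0.58, the D8 call being lost in 2 of 8 other settings), led by Nes and Sox2, with Olig1 at 7.67 against 0.146 CPM at D4 and 21.5 against 0.383 CPM at D8. The reporter of Nes defined the fractions, so the rise of that member was fixed by the sorting. Neuronal genes were higher with 9 and 8 of 17 members (medians 1.48 and 0.74, the D8 call being lost in 3 of 8 other settings), and Tubb3, a neuronal tubulin gene, was at 199 against 35.6 CPM at D4. The oligodendrocyte list was higher with 6 of 13 members on both days (medians 0.77 and 0.82). Macrophage markers were higher in the GFP-positive fraction as well, with 9 and 8 of 12 members (medians 1.80 and 1.5), Lyz2 at 185 against 14.5 CPM and Cd68 at 47.8 against 9.73 CPM at D4.

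Lower in the GFP-positive fraction were 14 and 20 of 25 fibroblast genes (medians -1.51 and -1.88; Dcn 311 against 3053 CPM and Twist1 9.86 against 104 CPM at D4). In the same list 4 and 3 members were higher, Fn1 at 853 against 308 CPM and Postn at 1025 against 352 CPM at D4. Lower as well were 11 and 13 of 18 TGF-beta and contractile genes (medians -1.68 and -1.71; Acta2 93.3 against 636 CPM at D4), with 2 higher on each day. Inflammatory genes fell with 7 and 8 of 16 members (medians -0.77 and -0.87), Cxcl5 standing at 10.2 against 164 CPM at D4. Growth factor genes were lower in 16 and 15 of 36 members and higher in 7 and 6 (medians -0.48 and -0.72). Inhba and Bmp4 went with the lower ones (9.12-fold and 10.4-fold at D4), Fgf5 and Lif with the higher. Matrix proteases (6 and 10 of 16 members, 3 higher on each day; medians -0.87 and -1.30), receptors and targets of IL6 and LIF (6 of 14 on each day, medians -0.47 and -0.90, the D4 call being lost in 3 of 8 other settings) and Hox genes (9 and 8 of 36, 3 and 2 higher, medians -0.37 and -0.62) were lower on both days. At D4 Mmp3 stood at 41.8 against 279 CPM, Osmr, a receptor gene of that cytokine family, at 103 against 296 CPM and Hoxc8 at 7.49 against 51.0 CPM. Mitochondrially encoded genes were lower in 12 of 13 members on both days (medians -1.46 and -1.41). They made up 0.834% and 1.09% of the GFP-positive against 2.79% and 2.77% of the GFP-negative counts. Ribosomal protein, oxidative phosphorylation and p53 genes were called lower at D4 and not at D8 (medians -1.02, -1.28 and -0.71). Lists called lower at D8 and not at D4 were hedgehog (median -1.11), cholesterol synthesis (-0.92), Wnt targets (-0.61), hypoxia and glycolysis (-1.07), immediate early (-0.86) and endothelial genes (-0.40), the last call being lost in 6 of 8 other settings. The differences between the days were not tested. Adipocyte and epithelial genes were lower on both days (medians -0.91 and -1.12, -0.28 and -0.29).

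At D4, 2882 genes were higher and 1311 lower of 11360 (68.7% higher) and at D8 2306 and 1381 of 11351 (62.5%), with median differences of 0.34 and 0.22. With median ratio scaling 52.2% and 50.4% of the changed genes were higher, and with TMM scaling 51.3% and 52.3%. The differences of D4 and D8, which share no library, correlated across 11634 genes with Pearson r of 0.92 and Spearman rho of 0.91, genes not being independent replicates. Both pairs were sorted by the same reporter, and whether D4 and D8 came from separate cultures is not known here. Agreement between the days therefore does not stand for replication. On both days 2099 genes were higher and 956 lower, against 593.2 and 165.7 for independent lists. In contrast, 4 genes went opposite ways: Gm2000, Idi1, Mex3d and Spon1.

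**Figure D2:**
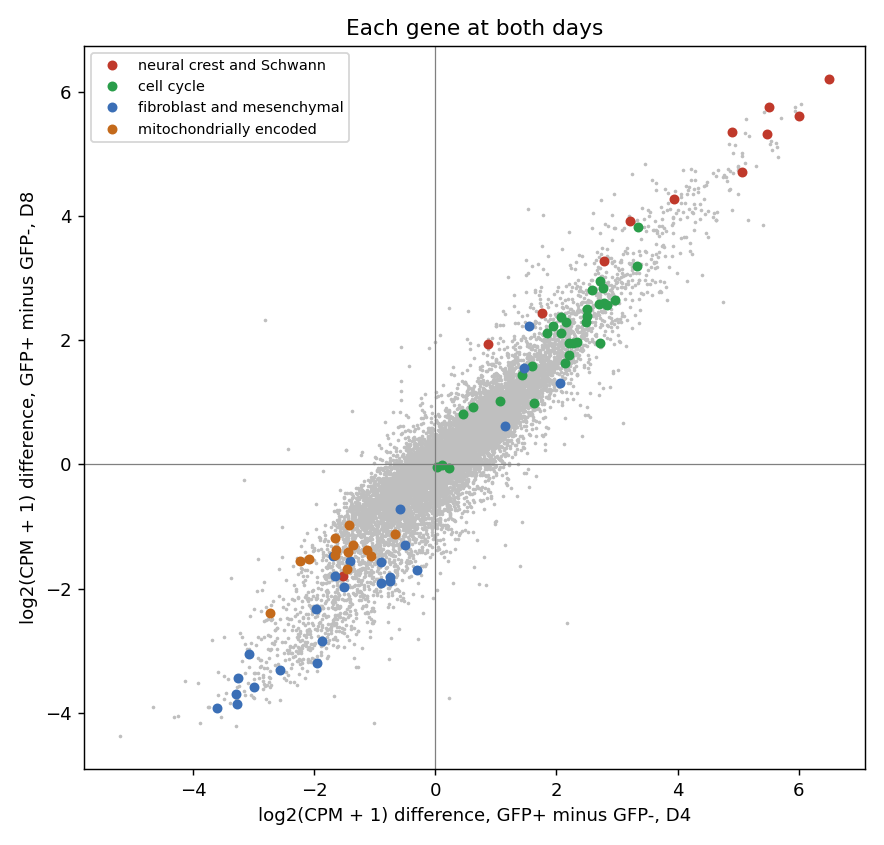
Difference of log2(CPM + 1) between the GFP-positive and GFP-negative libraries at D4 (horizontal axis) and at D8 (vertical axis), each point a gene, with 4 gene lists in colour. Neural crest and Schwann genes lie at the upper end (list medians 3.94 and 4.27) and fibroblast genes towards the lower end (-1.51 and -1.88).

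**Figure D3:**
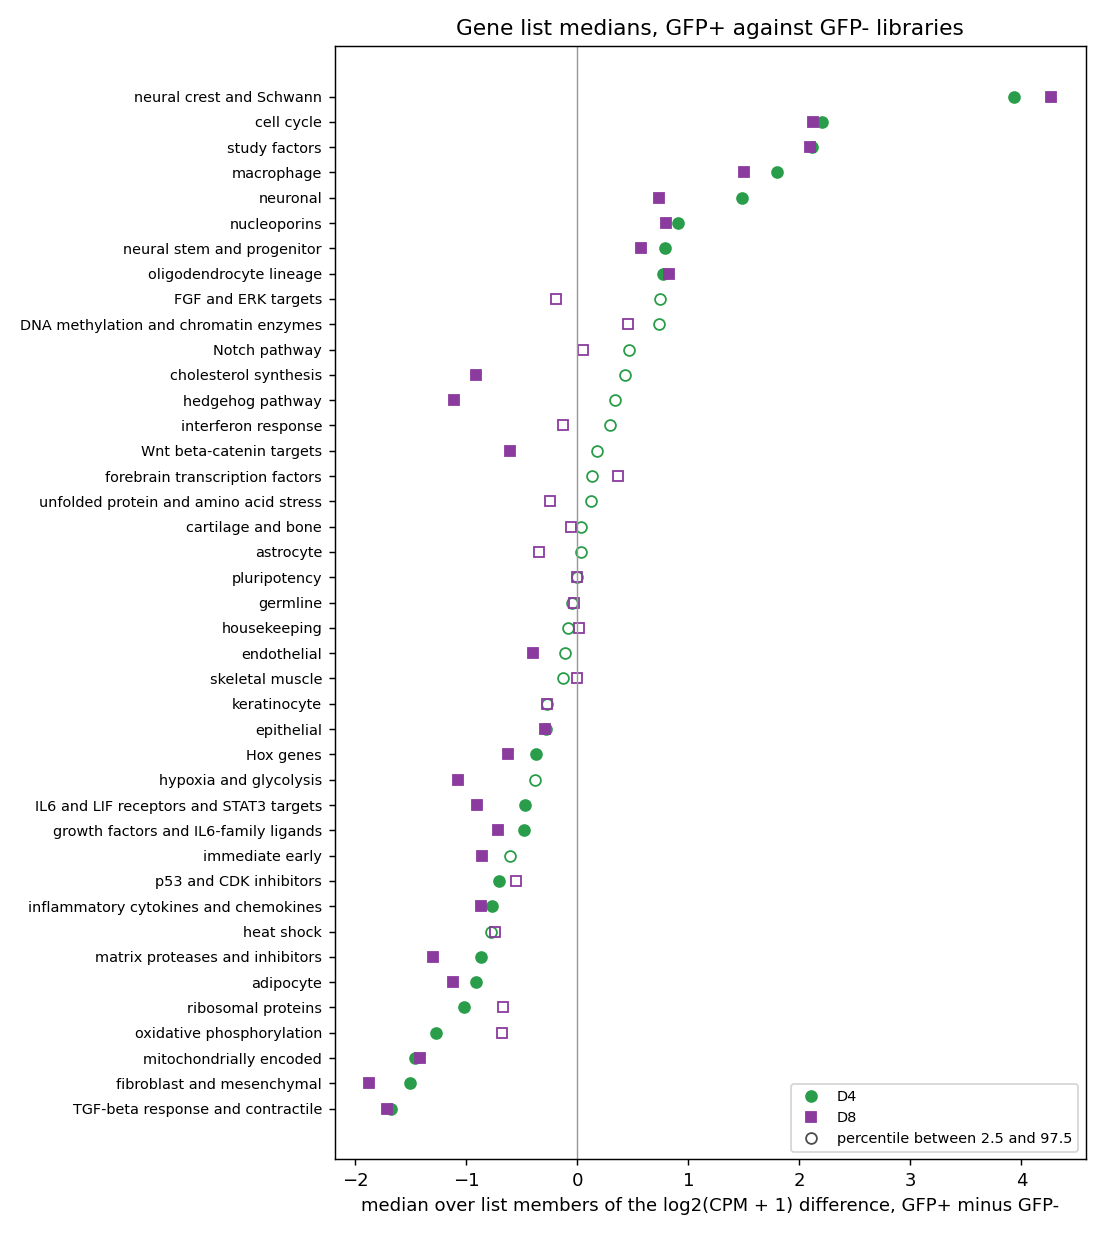
Median difference of log2(CPM + 1) over the members of each list between the GFP-positive and GFP-negative libraries, circles for D4 and squares for D8; filled marks are medians in the outer 2.5% of random lists on either side. The neural crest and Schwann list (3.94 and 4.27) and the cell cycle list (2.20 and 2.12) lie at one end and the TGF-beta list (-1.68 and -1.71) at the other.

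Between D4 and D8 the GFP-positive library kept most of its profile, with 142 genes higher and 166 lower of 11106. Genes of the amino acid stress response fell, Trib3 from 51.8 to 1.77 CPM, Chac1 from 36.0 to 2.49 CPM and Asns, the asparagine synthetase gene, from 594 to 119.5 CPM (8 of 13 list members lower, median -1.12). S100b and Gfra3, genes of glia and of the GDNF receptor family, rose from 3.82 to 16.5 and from 24.5 to 83.5 CPM. The neural crest and Schwann list was higher (3 of 13 members past 2-fold, median 0.27). Insig1 rose from 12.6 to 36.0 CPM and Msmo1, a sterol oxidase gene, from 94.7 to 210.4 CPM, with 17 of 19 cholesterol synthesis genes above 0 (median 0.53). Targets of FGF and ERK fell with 3 of 15 members (median -0.56; Etv5 24.8 to 7.10 CPM). Jag1, a Notch ligand gene, fell from 15.4 to 3.12 CPM (Notch list median -0.39). The remaining calls were higher medians of the immediate early, mitochondrially encoded and oligodendrocyte lists (0.43, 0.40 and 0.17, the last call being lost in 5 of 8 other settings) and lower medians of the interferon and TGF-beta lists (-0.49 and -0.21). The higher genes were 46.1% of those changed, 62.5% with median ratio scaling and 53.3% with TMM scaling.

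In the GFP-negative library 16 of 19 cholesterol synthesis genes rose between D4 and D8 (median 1.61), Insig1 from 5.78 to 68.7 CPM or 11.9-fold (95% interval 10.1 to 14.1), and Idi1, an isoprenoid enzyme gene, from 19.8 to 149 CPM. Wnt targets rose with 8 of 16 members (median 0.96; Notum 0.146 to 5.53 CPM) and hedgehog genes with 3 of 10 (median 0.78; Hhip 2.96 to 18.0 CPM). Fibroblast genes rose with 5 of 25 members (median 0.37; Snai1 7.46 to 27.9 CPM) and matrix proteases with 3 of 16 (median 0.38; Mmp13 440.2 to 1245 CPM). Trib3 fell here too, from 32.6 to 1.96 CPM (unfolded protein list median -0.51). Smaller called shifts were upward for immediate early, hypoxia, and cartilage and bone genes (0.53, 0.31 and 0.28) and downward for oxidative phosphorylation, interferon and cell cycle genes (-0.63, -0.23 and -0.15, the last 2 calls being lost in 3 and 2 of 8 other settings). In all, 397 genes were higher and 159 lower (71.4% higher; 76.5% with median ratio and 61.9% with TMM scaling).

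Primary NSC were set against D0 to mark the distance between the start and the intended end of the conversion. Dlx1, a forebrain transcription factor gene, was at 1058 CPM in NSC and 0.572 CPM at D0, Olig1 at 395 and 0.0544 CPM, Bcan, a brain proteoglycan gene, at 327 and 0.299 CPM, and Dcx, a gene of young neurons, at 497 and 0.221 CPM. Col1a1 was at 5.87 CPM in NSC and 5658 CPM at D0, Postn at 0.895 and 2393 CPM, and Lox, the lysyl oxidase gene, had 0 counts in NSC against 2899 CPM. Of the lists, 19 of 20 neural stem and progenitor genes (median 5.50), 15 of 17 neuronal genes (5.71) and 9 of 10 forebrain transcription factors (5.53) were higher. Of 14 Notch genes 12 (3.22; Hes5 89.3 CPM against 0 counts) and 11 of 13 oligodendrocyte genes (2.89) were higher. Cell cycle (29 of 32; median 2.28), chromatin enzyme (19 of 22; 2.28; Tet1 76.4 against 2.93 CPM) and nucleoporin genes (20 of 30; 1.61) were higher too. Immediate early genes had a median of 0.99, a call lost in 4 of 8 other settings, among them TMM scaling, where it turned to -0.059.

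Fibroblast genes were lower in NSC in 22 of 25 members (median -5.68), TGF-beta and contractile genes in 17 of 18 (-4.50; Thbs1 0.597 against 3330.3 CPM) and matrix proteases in 12 of 16 (-3.71). Genes of the p53 list were lower in 12 of 16 (-2.12; Cdkn1a 37.1 against 1398 CPM) and Hox genes in 22 of 36, some of them under 5 CPM in both libraries (-1.38; Hoxb9 0.329 against 34.1 CPM). Growth factor (-1.28), hypoxia (-1.65), inflammatory (-1.09, with 6 members higher and 8 lower, turning to 0.070 over all members), mitochondrially encoded (-1.91), IL6 and LIF (-0.99), interferon (-0.76), adipocyte (-1.48), cholesterol (-0.47) and cartilage and bone lists (-0.039, a call lost in 4 of 8 other settings and turning to 0.22 over members at 5 CPM) had lower medians than their random counterparts. Epithelial and skeletal muscle lists had medians of 0.011 and 0.070, low among random lists at percentiles 0.450 and 0.440, and both medians turned negative with median ratio (-0.14 and -0.14), TMM and quantile scaling. Macrophage markers were present in NSC beside these groups, with Csf1r at 245 CPM, C1qb at 109 CPM and Itgam at 33.8 CPM. The median gene lay 1.00 above D0, with 6445 genes higher and 2242 lower of 12906 (74.2% higher), 62.4% with median ratio and 49.3% with TMM scaling.

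GFP-positive cells of D8 differed from NSC in 2297 genes higher and 4382 lower. They held neural crest and matrix genes that were far lower in NSC, such as Cdh19 (553 against 0.20 CPM), Foxd3, a neural crest transcription factor gene (111 CPM against 0 counts), and Postn, a matrix gene (1099 against 0.895 CPM). They held less of forebrain and neuronal genes, with Dlx1 at 18.9 against 1058 CPM, Dlx2 at 21.3 against 734 CPM and Dcx at 0.553 against 497 CPM. Of the lists, 10 of 10 forebrain (median -4.55), 18 of 20 neural stem and progenitor (-4.60), 14 of 17 neuronal (-4.68) and 9 of 14 Notch (-2.78) genes were lower. So were 28 of 32 cell cycle (-1.74) and 14 of 22 chromatin enzyme genes (-1.51), as well as immediate early and heat shock genes (-0.70 and -1.12). Neural crest (3.11), fibroblast (3.46), p53 (2.36), matrix protease (2.29), IL6 and LIF (1.84), Hox (1.10), TGF-beta (1.07), growth factor (0.60) and epithelial lists (0.16, -0.22 as a mean) had higher medians, the last with a mean of -0.22. The median gene lay -0.36 from NSC, and 34.4% of the changed genes were higher, 36.3% with median ratio and 52.8% with TMM scaling.

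Across 17041 genes the libraries nearest to each other were the GFP-positive ones of D4 and D8 and the D1 and D2 ones (Spearman rho 0.988 for each pair). With NSC, rho was 0.765 and 0.762 for the GFP-positive libraries of D4 and D8, 0.701 and 0.698 for the GFP-negative ones, 0.691 for D0, 0.687 for D1, 0.680 for D2 and 0.661 for GF. Pearson r was 0.760, 0.756, 0.696, 0.691, 0.683, 0.678, 0.671 and 0.650 in the same order. Genes at least 4-fold apart between NSC and D0 numbered 3915 on the NSC side and 1149 on the D0 side. Of the NSC-high genes, 52.6% were 2-fold above D0 in the GFP-positive D4 library (25.6% of other genes matched on their D0 level), 50.7% at D8 (23.0%), 12.9% and 19.2% in the GFP-negative libraries (9.78% and 13%), 7.71% and 6.51% at D1 and D2 (6.09% and 6.49%) and 37.4% in GF (26.8%). With median ratio scaling these shares were 36.8% and 38.2% in the GFP-positive libraries and 36.6% in GF, so that the distance between the raw shares rested on the scaling. The shares of matched genes under that scaling are not given, so whether the distance beyond matched genes closes too is not known. Of the D0-high genes, 49.9% and 53.2% were 2-fold below D0 in the GFP-positive libraries (14.4% and 16.8% of matched genes), 20.3% and 21.1% in the GFP-negative ones (3.96% and 5.17%), 17.4% and 18.9% at D1 and D2 (4.80% and 4.94%) and 37.2% in GF (24.5%), with 65.1% and 64.6% against 39.2% under median ratio scaling. D0 entered both the choice of these genes and the comparison, which by itself raises both shares. D0 redrawn with counting noise gave 0 of 3915 and 0 of 1149 (upper 95% bounds 0.0942% and 0.321%). This redraw holds counting noise alone, so it does not give the shares that a separate library of the same cells would show.

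**Figure D4:**
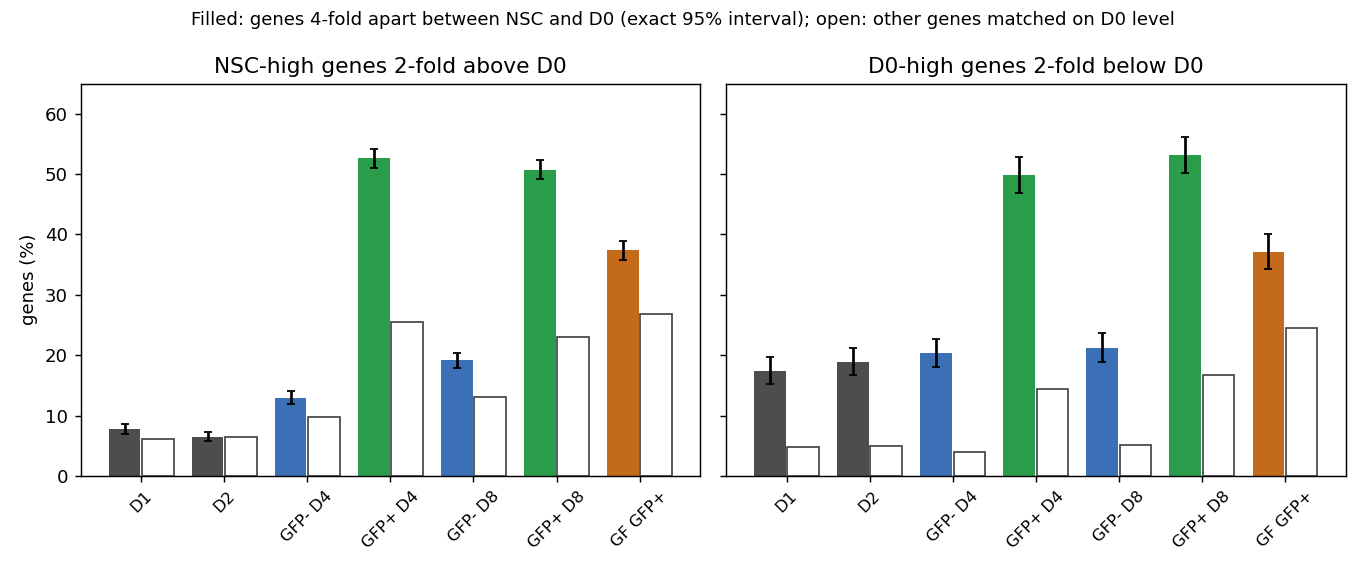
Filled bars give the percent of the 3915 NSC-high genes 2-fold above D0 (left) and of the 1149 D0-high genes 2-fold below D0 (right) in each other library, with exact 95% intervals; open bars give other genes matched on their D0 level. The GFP-positive libraries reach 52.6% and 50.7% on the left, against 37.4% in GF, and 49.9% and 53.2% on the right. The distance on the left between the raw shares closes with median ratio scaling (36.8% and 38.2% against 36.6%), for which matched shares are not given.

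The GF library came from cells given growth factors in place of the chemicals. Its labels give no day of collection, and the series holds no GFP-negative library of that protocol. Its Y-linked genes lay below those of the other fibroblast-derived libraries, so its cells may come from other embryos. Differences of GF from the other libraries therefore cannot be put down to the growth factors alone. Against D0, GF was led by genes of defence and inflammation. Irf7, a master regulator gene of interferon, stood at 1101 against 8.79 CPM or 125-fold (95% interval 112 to 140.2), Ccl5, a T cell chemokine, at 459.5 against 0.327 CPM and Lcn2, an iron-binding defence gene, at 649 CPM against 0 counts. Mmp3, a matrix protease gene, stood at 6547 against 33.4 CPM. Sox2, Nes and Olig1 rose to 13.4, 51.0 and 12.4 CPM, below their NSC levels, and Msi1 to 19.4 CPM, above its 11.3 CPM in NSC, while Acta2 fell to 166 CPM. Of the lists, 15 of 15 interferon genes (median 4.02), 12 of 16 inflammatory genes (2.70), 12 of 14 IL6 and LIF genes (1.78) and 12 of 15 FGF and ERK targets (1.85) rose. So did 13 of 20 neural stem and progenitor genes (1.68), 19 of 32 cell cycle genes (1.13) and 12 of 25 fibroblast genes (0.77, with 5 lower; Lum 1420.2 against 97.49 CPM).

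Astrocyte (1.87; Gfap 20.7 against 0.381 CPM), hedgehog (1.73; Ptch1 28.2 against 1.47 CPM), hypoxia and glycolysis (1.22), chromatin enzyme (1.14), matrix protease (0.95, 8 higher and 4 lower), ribosomal protein (0.68), skeletal muscle (1.22) and cartilage and bone lists (0.84, a call lost in 4 of 8 other settings) also had higher medians in GF than at D0. Lower medians were those of oxidative phosphorylation (-1.26), mitochondrially encoded (-1.58), unfolded protein (-1.42), TGF-beta (-1.30, with 5 members higher and 10 lower), macrophage (-1.10), keratinocyte (-0.77), adipocyte (-0.71, a call lost in 3 of 8 other settings) and Hox genes (-0.24). Of 36 Hox genes 5 were higher, Hoxa2 going from 1.35 to 19.3 CPM, and 13 lower, Hoxc8 going from 42.5 to 0.319 CPM. Rps12 (292 CPM in GF against 0 counts at D0), H2-Q4 (631 against 1.17 CPM), H2-Q6 (517 against 0.841 CPM) and Hist1h2ap (0 counts after rounding against 179 CPM) were among the most different genes, and all belong to families of near-identical copies, so that their values are uncertain. In all, 3663 genes were higher and 1825 lower (66.7% higher; 62.7% with median ratio and 56.0% with TMM scaling), around a median of 0.30.

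Against the GFP-positive cells of D8, GF held lower levels of most neural crest and Schwann genes and more of fibroblast, interferon and inflammatory ones. Cdh19 stood at 0.361 CPM in GF against 553 CPM, Sox10 at 6.59 against 748 CPM and Fgf5 at 0.544 against 391 CPM. Thy1, a fibroblast surface gene, stood at 515 against 9.77 CPM and Isg15 at 633 against 1.84 CPM. The neural crest list was lower in 9 of 13 members (median -4.14) and macrophage markers in 8 of 12 (-1.80; Cd68 2.62 against 45 CPM). Interferon (14 of 15 higher; median 5.17), fibroblast (20 of 25; 3.21), inflammatory (11 of 16; 2.86), ribosomal protein (21 of 25; 1.60) and TGF-beta genes (12 of 18; 1.53) were higher. So were the medians of skeletal muscle (1.90), hypoxia (1.81), growth factor (1.32), IL6 and LIF (1.30), matrix protease (0.96), cholesterol (0.79), neural stem and progenitor (0.77), FGF and ERK (0.69), cartilage and bone (0.63) and cell cycle genes (0.32). The neural stem and progenitor call was lost in 4 of 8 other settings, and 7 of 20 members were higher (Slc1a3 59.3 against 2.42 CPM) and 4 lower (Nes 51.0 against 721 and Sox2 13.4 against 130.3 CPM). In all, 2549 genes were higher and 3341 lower (43.3% higher; 58.9% with median ratio and 54.4% with TMM scaling), around a median of -0.27.

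Against NSC, GF held 24 of 25 fibroblast genes higher (median 6.58; Dcn 2732 CPM against 0 counts) and 17 of 20 neural stem and progenitor genes lower (-4.12; Ptprz1 6.09 against 525 CPM). Neuronal (14 of 17; -6.04), forebrain (7 of 10; -4.20), oligodendrocyte (-3.52), Notch (-3.27), cell cycle (-1.48), immediate early (-1.18) and macrophage lists (-3.53; Csf1r 1.08 against 245 CPM) were lower. Higher medians were those of interferon (5.36), inflammatory (4.69), IL6 and LIF (3.90), matrix protease (3.63), TGF-beta (2.89), hypoxia (2.27), growth factor (2.21), ribosomal protein (2.20), p53 (1.81), FGF and ERK (1.43), skeletal muscle (1.22), hedgehog (1.08), Hox (0.96), Wnt (0.60) and cartilage and bone genes (0.064, a call lost in 5 of 8 other settings). The median gene lay -0.67 from NSC, with 2797 genes higher and 5600 lower (33.3% higher; 44.7% with median ratio and 54.2% with TMM scaling). Lists of pluripotency, germline and housekeeping genes were not called shifted in any of the 15 comparisons.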

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

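The tests of technical explanations in this part were chosen after their results were seen, except a first form of the test of another transcript set for the GF library.

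The differences of opposite direction that follow were picked out because a list median or gene moved one way in one pair of libraries and the other way in the matching pair, and none of these differences was tested. The signs are taken against 0 and not against the shift of all genes. No list was called shifted on both sides of its pair. Between the D4 fractions, for example, the medians of Wnt, hedgehog and cholesterol genes lay at percentiles 46.25, 71.07 and 70.03 of their random lists. Between the GFP-positive and GFP-negative fractions, medians at D4 and D8 were 0.18 and -0.61 for Wnt targets (0.79 apart), 0.34 and -1.11 for hedgehog genes (1.45 apart) and 0.43 and -0.92 for cholesterol synthesis (1.34 apart). Between D8 and D4, the GFP-positive and GFP-negative medians were -0.06 and 0.37 for fibroblast genes (a difference of -0.43), -0.20 and 0.78 for hedgehog genes (-0.97) and -0.08 and 0.31 for hypoxia and glycolysis (-0.38).

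Against D0, the D4 medians of the GFP-positive and GFP-negative fractions were 0.98 and -1.25 for cell cycle genes (a difference of 2.23), 0.69 and -0.94 for macrophage markers (1.63), -0.08 and 1.23 for immediate early genes (-1.31) and -1.12 and 0.23 for oxidative phosphorylation (-1.35). They were -0.29 and 0.69 for p53 genes (-0.98), -0.43 and 0.29 for inflammatory genes (-0.72), -0.34 and 0.30 for growth factor genes (-0.64), -0.58 and 0.02 for matrix proteases (-0.60) and -0.41 and 0.12 for Hox genes (-0.53). Il6 itself moved by -1.46 in the GFP-positive and 1.68 in the GFP-negative D4 library (-3.14). At D8 the medians were 0.90 and -1.17 for cell cycle genes (2.07), 0.51 and -0.59 for macrophage markers (1.09), -0.85 and 0.18 for hypoxia and glycolysis (-1.03) and -0.13 and 0.73 for hedgehog genes (-0.86). They were -0.11 and 0.74 for p53 genes (-0.85), -0.47 and 0.31 for growth factor genes (-0.78), -0.39 and 0.14 for Hox genes (-0.53) and -0.22 and 0.01 for cartilage and bone genes (-0.23). The median of all genes lay higher in the GFP-positive than in the GFP-negative libraries against D0 (0.66 against 0.30 at D4). Opposite signs therefore do not by themselves mean opposite shifts against other genes. In the GFP-negative fraction, the matrix protease median at D4 lay at percentile 15.65 and the Hox median at D8 at percentile 34.89.

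Neural crest and Schwann genes were high in both GFP-positive libraries, and a set of 78 genes at least 16-fold higher in the GFP-positive than the GFP-negative library on both days, 6 of them in the neural crest and Schwann list, had a median ratio of D0 to the GFP-positive D4 library of 1.5% (quartiles 0.970% and 3.11%, highest 7.88%). Carried-over GFP-positive reads, as the only source of these genes in the D0 and D2 libraries, would keep 1 ratio between those libraries. Only 26.9% of the set (21 genes) had intervals holding the median ratio of 1.26, which argues against carry-over as the only source. Expression by the D0 and D2 cells themselves would break the ratio as well, so the test cannot exclude carry-over beside it. Cells with the whole profile in the starting culture at one share could not be told apart from a rise during treatment, because 64.1% of the set (50 genes) reached within 2-fold of the median, short of the 80% that source would need and above the 50% that would exclude it. A first version of the test, at 4-fold, gave 66 of 78, but the selection of the set bounds its upper side. A biological rise under VCR was not tested and stays open.

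The GF library, which differed from the others by its interferon genes, may come from other embryos: its 4 Y-linked genes lay below each of the 7 other fibroblast-derived libraries, at 0.145 (Ddx3y), 0.193 (Kdm5d), 0.124 (Eif2s3y) and 0.116 (Uty) of their median, as a lower share of male cells would give. A count of genes at 0 could not tell another transcript set or counting from a difference between the cells. It found 2 genes at 0 here and at 10 CPM or more in each other library, against 0 such genes for each of the 7 others. That was short of the 10 that would speak for another transcript set. The reverse, 10 CPM or more here and 0 in the other 8 libraries, held for 7 genes, Rps12 among them. It held for 0 genes in each of the 7 other fibroblast-derived libraries and for 3 in NSC. Rps12l1 had 0 counts here and 9.54 CPM or more in each other library. The share of estimated counts within 0.001 of a whole number was 58.95% here and 50.96% or less in each other library. These values go with another transcript set or counting for this library. They were not tested against a difference between the cells, so the question stays open. The first form of the test of genes at 0, against all libraries, was void, since the 27 genes at 0 only in NSC include fibroblast genes such as Dcn and Lum. If the library came from other embryos, their effect and that of the growth factors on the interferon genes cannot be separated, and this was not tested.

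Mitochondrially encoded transcripts were lower in the GFP-positive libraries. Both fractions were sorted, and on each day the GFP-negative library held at least 2.53 times the share of its GFP-positive counterpart (2.79% against 0.834% and 2.77% against 1.09%), which argues against sorting as such. Sorting that acts differently on the fractions cannot be told apart from a difference between the cells. The series holds no unsorted D4 or D8 library, and the GFP-negative 2.77% lay between unsorted D0 (3.39%) and unsorted D1 and D2 (1.96% and 1.94%). Earlier forms of the test, against D2 alone and then against these 3 libraries, had spoken against sorting and left it open. Scaling to the library total is argued against too, since the list median stayed at -1.62 or below on both days with median ratio scaling, and a difference between the cells was not tested.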

How the results depend on the processing

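TMM scaling, and quantile normalization of the list medians, were chosen after the results were seen, and the other settings were planned. A count of genes was taken as moved beyond 1.5 times its value, a correlation beyond 0.05, a share beyond its exact 95% interval and a study factor when it crossed 2-fold. By these limits, of 388 values for 85 leading results under other settings, 284 stayed and 104 moved. Of 2160 list medians, 2022 kept their call, 123 lost it and 15 changed sign. Of 5655 differences of named genes, 5489 kept their side of 2-fold, 122 dropped under it and 44 passed it. Calls lost or reversed in at least 4 of 8 settings were those of cartilage and bone in GFP-positive D4 and D8, GFP-negative D4, NSC and GF against D0 and GF against NSC, of skeletal muscle in GFP-positive D4 and NSC against D0, of matrix proteases in GFP-positive D4 against D0, and of epithelial and immediate early genes in NSC against D0. So were those of endothelial genes between the D8 fractions, of neural stem and progenitor genes in GF against GFP-positive D8 and of oligodendrocyte genes in GFP-positive D8 against D4. Lost in 3 settings were those of IL6 and LIF genes between the D4 fractions, neuronal genes between the D8 fractions, interferon genes in GFP-negative D8 against D4 and adipocyte genes in GF against D0, and 16 further calls were lost in 2. The setting that takes each column of a sample alone was not run, because each sample has 1 column. A paired model of the fractions over D4 and D8, with the days in the place of replicates, was not run.

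With a pseudocount of 5, which shrinks differences of low genes, the counts of genes fell to 398 higher and 361 lower for D1 against D0, 433 higher and 414 lower for D2 against D0, 649 higher for GFP-negative D4 against D0 and 1164 higher for GFP-negative D8 against D0. They were 86 higher and 65 lower for GFP-positive D8 against D4 and 247 higher and 70 lower for GFP-negative D8 against D4. With median ratio scaling the counts were 2500 higher and 2381 lower for GFP-positive D4 against D0, 2579 higher and 2427 lower for GFP-positive D8 against D0, 637 higher and 877 lower for GFP-negative D4 against D0 and 1140 higher and 1077 lower for GFP-negative D8 against D0. They were 109 lower for GFP-positive D8 against D4. With quantile normalization they were 2312 higher and 2269 lower for GFP-positive D4 against D0, 2308 higher and 2339 lower for GFP-positive D8 against D0, 631 higher for GFP-negative D4 against D0 and 997 higher for GFP-negative D8 against D0. They were 1862 higher and 1979 lower for the D4 fractions, 95 lower for GFP-positive D8 against D4 and 3621 lower for NSC against D0. With TMM scaling they were 2557 higher and 2341 lower for GFP-positive D4 against D0, 2448 higher and 2537 lower for GFP-positive D8 against D0, 704 higher for GFP-negative D4 against D0 and 1002 higher and 1235 lower for GFP-negative D8 against D0. They were 3980 higher and 4093 lower for NSC against D0, 3479 higher for GFP-positive D8 against NSC and 3532 lower for GF against NSC. The scalings move the median gene and with it the split of higher and lower genes, and beyond that the cause was not tested.

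Correlations over genes with 5 CPM or more were lower, and the cause was not tested. Pearson r with NSC was 0.525 for D0, 0.516 for D1, 0.507 for D2, 0.535 for GFP-negative D4, 0.625 for GFP-positive D4, 0.525 for GFP-negative D8, 0.621 for GFP-positive D8 and 0.457 for GF. Pearson r with D0 was 0.834 for GFP-positive D4, 0.820 for GFP-positive D8 and 0.803 for GF. Spearman rho with NSC was 0.549 for D0, 0.544 for D1, 0.532 for D2, 0.562 for GFP-negative D4, 0.661 for GFP-positive D4, 0.560 for GFP-negative D8, 0.656 for GFP-positive D8 and 0.499 for GF. Spearman rho with D0 was 0.833 for GFP-positive D4, 0.818 for GFP-positive D8 and 0.789 for GF.

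Shares of genes moved towards NSC changed with the settings as follows. The share of NSC-high genes raised on the 8-fold axis was 10.1% in D1, 8.5% in D2, 14.3% in GFP-negative D4 and 40.1% in GF. With a pseudocount of 5 the share of NSC-high genes raised was 3.01% in D1, 2.44% in D2, 5.80% in GFP-negative D4, 48.4% in GFP-positive D4, 10.2% in GFP-negative D8, 46.3% in GFP-positive D8 and 30.5% in GF. With median ratio scaling the share of NSC-high genes raised was 9.14% in D1, 7.87% in D2, 8.90% in GFP-negative D4, 36.8% in GFP-positive D4, 14.1% in GFP-negative D8 and 38.2% in GFP-positive D8, beside 36.6% in GF. With TMM scaling the share of NSC-high genes raised was 10.2% in D1, 9.10% in D2, 9.83% in GFP-negative D4, 38.1% in GFP-positive D4, 13.4% in GFP-negative D8, 37.5% in GFP-positive D8 and 34.0% in GF. The share of D0-high genes lowered on the 8-fold axis was 23.7% in D2, 28.8% in GFP-negative D4, 58.3% in GFP-positive D4, 27.3% in GFP-negative D8, 60.2% in GFP-positive D8 and 40.8% in GF. With a pseudocount of 5 the share of D0-high genes lowered was 53.6% in GFP-positive D4. With median ratio scaling the share of D0-high genes lowered was 23.7% in GFP-negative D4, 65.1% in GFP-positive D4, 27.8% in GFP-negative D8 and 64.6% in GFP-positive D8. With TMM scaling the share of D0-high genes lowered was 13.1% in D1, 14.6% in D2, 61.2% in GFP-positive D4, 27.5% in GFP-negative D8, 63.1% in GFP-positive D8 and 44.2% in GF. The cause was not tested.

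In NSC against D0 the epithelial list median of 0.01 became -0.15 with a pseudocount of 0.1, -3.03 over members at 5 CPM, -0.14 with median ratio scaling, -0.30 with TMM scaling, -0.36 with quantile normalization and -0.53 as a mean. In that comparison the skeletal muscle median became -0.97 over members at 5 CPM, -0.14, -0.42 and -0.83 with median ratio, TMM and quantile scaling, the cartilage and bone median became 0.22 over members at 5 CPM, the inflammatory median 0.070 over all members, and the immediate early median -0.059 with TMM scaling. The epithelial median of GFP-positive D8 against NSC became -0.22 as a mean, and the hypoxia median of GFP-negative D4 against D0 became 0.019 with quantile normalization. Most of these medians lay near 0, and the cause was not tested. The difference of Nup210 between the D4 fractions went from 1.07 to 0.90 with median ratio scaling and 0.93 with TMM scaling, and 2 in place of 4 genes went opposite ways at D4 and D8 with a pseudocount of 5, for which the cause was not tested. Depth limits what a count of 0 excludes, with 3 counts at 0.149 CPM in NSC, the shallowest library.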

Other observations

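Every gene in this part was chosen after its values were seen. H2-K1, a class I antigen presentation gene, stood at 3712 CPM in GF against 119 CPM at D0 and 254 CPM in the GFP-positive D8 library, and Tap1, a peptide transporter gene, at 259 against 18.0 and 24.1 CPM. H2-D1 stood at 3744 against 414 CPM and B2m, the shared light chain gene, at 3844 against 2191 CPM, the last under 2-fold. H2-Q7 was at 643 against 2.84 CPM and is uncertain because reads may be shared with its near-identical copies.

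Some ligand genes stood higher in the GFP-positive libraries, while the fixed growth factor list went the other way between the fractions, with 16 and 15 of 36 members lower and 7 and 6 higher. Gdnf, a neurotrophic factor gene, stood at 38.7 and 65.2 CPM at D4 and D8 against 2.19 and 4.68 CPM in the GFP-negative libraries, Tgfa, an EGF receptor ligand gene, at 23.3 and 53.4 against 2.71 and 3.11 CPM, and Pdgfa, a growth factor gene for oligodendrocyte precursors, at 127 and 159 against 31.0 and 22.2 CPM. In NSC, Tgfa stood at 57.1 and Pdgfa at 6.12 CPM, and Dhh and Gdnf had 0 counts. Rps12 stood at 292 CPM in GF and 0 counts in the other 8 libraries, while Rps12l1 had 0 counts in GF and 39.4 CPM at D0, which leaves both uncertain.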
